A study of Danio rerio with 16 samples.

How the data were processed

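Whole embryos of zebrafish were profiled by bulk RNA sequencing in 16 libraries. The libraries formed 4 groups of 4: wild-type siblings and mutants at 24 hours post fertilisation (hpf), called sib24 and mut24 here, and the same genotypes at 48 hpf, called sib48 and mut48. Per the labels, the mutants lacked function of 2 genes, lipf and pla2g15. The sample labels name the tissue "body" while the description of the series speaks of whole embryos, and how many embryos entered a library is not given in the sources used here. Nothing in the labels says whether the 4 libraries of a group came from separate clutches, so p-values measure only the spread between these libraries, which may be technical.

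The deposited file held whole-number read counts for 36109 genes, 1 column per library, and the authors had not normalised or pooled them. Per the submitters' processing notes, the reads had been processed with FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.10b and featureCounts 2.0.6 on genome build GRCz11. The annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here, so values of near-identical paralogs, of overlapping genes and of antisense pairs are uncertain. Per the labels, total RNA was extracted with TRIzol and made into libraries with the VAHTS Universal V8 RNA-seq kit. In units of 1e6 counts, libraries ran from 35.9 to 50.5. Counting intervals would cover counting error only, since the reads carry no molecular identifiers, and the spread between the 4 libraries was used as the error throughout.

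Genes were kept by the filterByExpr function of edgeR with the 4 groups, which left 24300 genes for testing and removed 11809. Counts were scaled by TMM factors. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, with 1 mean per group and no covariate, fitted to all 16 libraries so that the groups shared 1 estimate of the spread. Contrasts were mutants against siblings at each age, 48 against 24 hpf within each genotype, and the interaction of genotype and age. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values per group are TMM-scaled counts per 1e6 counts of a library (CPM), as mean and SD, and log2 fold changes come with their standard error (SE). On simulated counts with known changes, the test recovered 30.9%, 71.2% and 92.4% of genes changed by log2 0.5, 1 and 2 in the 24 hpf comparison, and 23.5%, 72.7% and 95.5% in the 48 hpf comparison. The changed genes were drawn from those with a mean of at least 1 CPM, and the simulated libraries varied gene by gene only. These shares may therefore be too high for weaker genes and for real libraries, in which genes move together.

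The design, the alternatives, the rule for naming genes and 39 gene lists were fixed before the data were examined. Of 1158 list entries, 1125 matched a gene of the file, 20 of them through a synonym. For each list the members called over all genes and those called with p-values adjusted over the list alone were counted. Lists of at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. In each genotype contrast the named genes were lipf, pla2g15, the 6 largest and 6 smallest log2 fold changes among called genes with a symbol, a mean of at least 1 CPM in the higher group and groups that did not overlap, and for each core list and each other list called by camera the 2 called members with the smallest p, or for a core list without any the 1 member with the smallest p. The contrast of ages took 4 largest, 4 smallest and 1 member per core list, and the interaction the 4 smallest p. Any other gene is said to have been chosen after its values were seen. The result for 1 gene is not reported here.

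The position of each library on the path from sib24 at 0 to sib48 at 1 was found by projecting its log2 CPM (prior count 2) on the difference of the sibling means, built without the library scored. Values per library were compared by an exact two-sided permutation test over 70 assignments, whose smallest possible p is 0.0286. Symbols were matched to a RefSeq gene table of assembly GRCz12tu, which is not the build of the counts. It was used only to tell which genes lie on the chromosome of lipf or of pla2g15 and in which order, and gave a chromosome for 79% of the tested genes and for 88.6% and 88.8% of the genes called at 24 and 48 hpf. Calls on these chromosomes were compared with calls elsewhere by Fisher's exact test, two-sided.

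The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in at least 4 libraries), a minimum absolute log2 fold change of 1, a fit of only the groups compared, the replicate number as a block, DESeq2 1.42.0, and leaving out each library in turn. Chosen after seeing the data were a yolk syncytial layer score as a covariate at 24 hpf, fits without the 4 libraries of 24 hpf with the lowest and without the 4 with the highest score, the removal of genes on the chromosomes of lipf and pla2g15, and the extension of the fit of only the groups compared to named genes and lists. At 24 hpf the fit without the 4 lowest kept only sib24 replicates 2 and 3 and mut24 replicates 1 and 3. The fit without the 4 highest kept only sib24 replicates 1 and 4 and mut24 replicates 2 and 4. The smallest chi-square between 2 libraries of a group was 18.1 per degree of freedom over 11821 genes, so no pair agreed within sampling noise and each library was counted once.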

Results

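The series measured RNA of zebrafish embryos as read counts per gene in mutants of lipf and pla2g15, which encode gastric lipase and a lysosomal phospholipase, and in their wild-type siblings. The title of the series concerns the mobilisation of yolk lipid, the transcription factor Hnf4 and lipoproteins, and the comparisons below ask which genes differed between genotypes at 24 and 48 hpf. Each of the 4 groups held 4 libraries. Mean depth in units of 1e6 counts was 39.5 ± 0.428 (SD, n = 4) in sib24, 41.6 ± 6.25 in mut24, 40.8 ± 2.46 in sib48 and 42.4 ± 2.34 in mut48. The first principal component of log2 CPM held 69.8% of the variance and parted the ages.

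The targeted gene lipf was lower in every mutant library than in every sibling library of its age. It stood at 14 ± 7.62 CPM (SD, n = 4) in sib24 and 1.51 ± 0.723 in mut24, and at 22.8 ± 6.62 in sib48 and 2.41 ± 0.431 in mut48. The fall was 9.32-fold at 24 hpf (log2 fold change -3.22, SE 0.372, edgeR adjusted p = 0.00119) and 9.45-fold at 48 hpf (-3.24, SE 0.361, edgeR adjusted p = 4.31e-05). The transcript of pla2g15 was not called at either age. It stood at 13.2 ± 7.23 CPM in sib24 against 10.1 ± 6.94 in mut24 (log2 fold change -0.40, SE 0.375, edgeR adjusted p = 0.71), and at 54.4 ± 10.4 in sib48 against 38.6 ± 7.6 in mut48 (-0.50, SE 0.36, edgeR adjusted p = 0.468). A mutation of the coding sequence need not lower the transcript, so pla2g15 does not check the labels here.

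**Figure D1:**
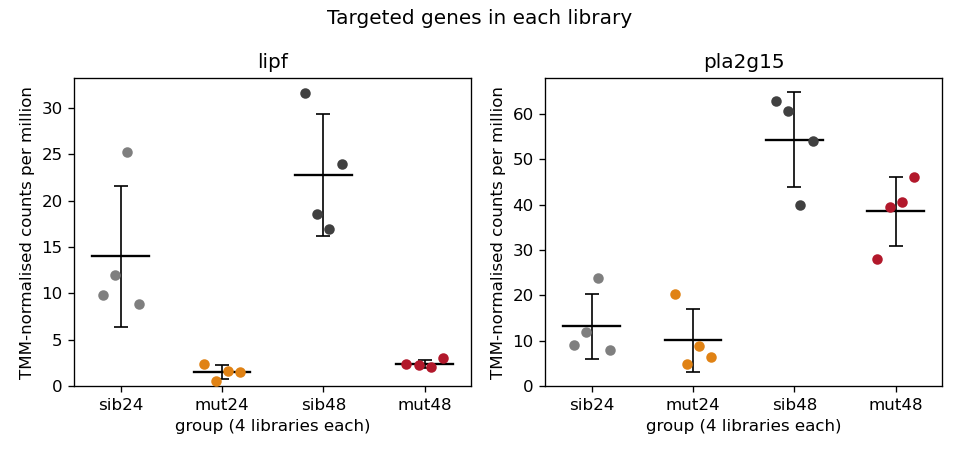
TMM-scaled CPM of lipf and pla2g15 on the vertical axis in each of the 16 libraries, by group; points are libraries, bars the mean and whiskers 1 SD (n = 4). All lipf values of mutants lie at or under 3.03 CPM and all values of siblings at or above 8.84 CPM, while pla2g15 values of the genotypes overlap.

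At 24 hpf, a few genes of fatty acid breakdown were lower in the mutants, and the regulators srebf1, srebf2 and insig1 of lipid and sterol synthesis were higher. Of 41 tested genes of fatty acid oxidation and Ppar targets, 5 were lower and 0 higher (1 higher and 10 lower when adjusted over the list alone). They included cpt1b, the muscle form of the enzyme that passes fatty acids into mitochondria, which fell 3.39-fold from 1.47 ± 0.626 to 0.426 ± 0.129 CPM (edgeR adjusted p = 0.00759), and pdk4, a kinase that shuts off pyruvate oxidation, which fell 1.8-fold (edgeR adjusted p = 0.00699). Of 29 genes of sterol synthesis, 3 were higher and 0 lower (6 and 0 when adjusted over the list alone), among them insig1 (1.7-fold, edgeR adjusted p = 0.0203) and the sterol regulator srebf2 (1.4-fold, edgeR adjusted p = 0.0259). Among 32 genes of fatty acid and triglyceride synthesis, 2 were higher and 2 lower (6 and 3 when adjusted over the list alone). The lipogenic regulator srebf1 rose 1.59-fold (edgeR adjusted p = 0.0111) and acacb, an acetyl-CoA carboxylase, fell 1.82-fold (edgeR adjusted p = 0.00119). Of 35 genes of glycolysis and gluconeogenesis 3 were lower and 0 higher (7 and 0 when adjusted over the list alone), including pfkma (2.14-fold) and tpi1b (1.37-fold). Camera called the first of these lists down (adjusted p = 0.00085), sterol synthesis up (adjusted p = 2.12e-05) and glycolysis down (adjusted p = 0.000816), and each reached only adjusted p = 0.695 with an estimated correlation.

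Markers of several tissues also differed at 24 hpf. Of 29 genes of epidermis, periderm and ionocytes 4 were higher and 0 lower (17 and 1 when adjusted over the list alone). The keratin gene krt5 rose 1.84-fold from 1899 ± 412 to 3499 ± 464 CPM (edgeR adjusted p = 0.00518) and cyt1l 1.65-fold. Of 42 skeletal muscle genes 4 were lower and 0 higher (9 and 0 when adjusted over the list alone), led by the calcium-binding parvalbumins pvalb2 (1.7-fold, edgeR adjusted p = 0.00518) and pvalb1 (1.98-fold, edgeR adjusted p = 0.00934). Of 18 pigment cell genes 1 was lower (10 when adjusted over the list alone), the pteridine enzyme gene gch2, which fell 1.56-fold. Of 31 circadian clock genes 3 were lower and 0 higher (8 and 0 when adjusted over the list alone), including per3 (1.78-fold) and tefa (1.62-fold). Of 17 heat shock genes 2 were higher and 0 lower (2 and 0 when adjusted over the list alone): hsp90aa1.2, which rose 2.62-fold, and the collagen chaperone gene serpinh1b, which rose 2.79-fold. Camera adjusted p-values were 1.24e-08 for epidermis, 1.37e-07 for muscle, 1.33e-06 for pigment cells, 3.97e-05 for the clock and 0.0326 for heat shock. With an estimated correlation the adjusted p-values were 0.695, 0.695, 0.447, 0.702 and 0.831 in that order.

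Camera also called 7 lists at 24 hpf in which at most 1 member was called. These were lysosomal genes up (only lipf itself was called, and it was lower), the endoplasmic reticulum and integrated stress response up (1 of 38 called, the chaperone gene dnajc3a, 1.48-fold higher), and with 0 members called neuronal genes, lens crystallins, erythroid genes, oxidative phosphorylation and cartilage, bone and matrix genes, all down. Their adjusted p-values ran from 0.000288 for neuronal genes to 0.0406 for oxidative phosphorylation and for cartilage, and with an estimated correlation the adjusted p-values ran from 0.695 for neuronal genes to 0.872 for oxidative phosphorylation. When adjusted over the list alone, 2 lysosomal genes were higher and 1 lower, and 3 stress response genes were higher and 0 lower. Lower in the same way were 2 neuronal genes, 2 cartilage genes and 1 gene of oxidative phosphorylation, with 0 higher, and 0 lens or erythroid genes were called. In the cartilage list the smallest p belonged to fmoda (edgeR adjusted p = 0.0699). In the main test of edgeR no member was called among lipoprotein genes (28 tested), Hnf4 and other hepatic transcription factors (25), yolk syncytial layer markers (23), hepatocyte and plasma protein genes (30), lipid droplet and lipolysis genes (13), the insulin and Igf axis (29), cell cycle genes (46) and myeloid genes (22), and camera called none of these lists. Over these 8 lists and the cartilage list, 20 of 249 members had an unadjusted p under 0.05 and DESeq2 called 4. The smallest-p members in that order were lcat, onecut1, gata6, uox, bscl2, gh1, top2a and mfap4, with edgeR adjusted p-values from 0.0936 for gh1 to 0.49 for gata6. For gh1, 0 reads in mut24 stood against 18 in sib24, which is at least 6.34-fold lower when 3 counts over the group are taken as the floor. The yolk syncytial layer list had a median log2 fold change of 0.23 and a mean of 0.18, the hepatocyte list 0.29 and 0.31, and camera's direction was down for both (adjusted p = 0.781 and 0.736). The lipoprotein list had a median of 0.11, a mean of -0.03 and the direction down (adjusted p = 0.736), and the Igf list a median of 0.02, a mean of -0.13 and the direction up (adjusted p = 0.866). With the yolk syncytial layer score as a covariate, chosen after seeing the data, edgeR called some lipoprotein genes lower in mut24. These were apoa4b.1 (log2 fold change -1.56, adjusted p = 0.00561), apoa4b.2 (-2.35, adjusted p = 0.0382) and apoba (-0.76, adjusted p = 0.0423). In the main test their edgeR adjusted p-values were 0.854, 0.646 and 0.93 in that order. The other lipoprotein genes were not called in the fit with the covariate. The score was the mean of a list that holds apoa4b.1 and apoa4b.2 themselves, and genotype may have moved the score. The calls with the covariate therefore do not settle whether genotype lowered these genes at 24 hpf. Without the 4 libraries lowest in yolk syncytial layer markers, chosen after seeing the data, the direction of the yolk syncytial layer list turned up (adjusted p = 0.000339), as did that of the hepatocyte list (adjusted p = 0.000219) and of oxidative phosphorylation (adjusted p = 0.0069). Without the 4 highest, also chosen after seeing the data, camera called the yolk syncytial layer (adjusted p = 2.18e-05), hepatocyte (adjusted p = 4.8e-06) and lipoprotein lists (adjusted p = 0.000162) down. The libraries were removed by the mean of the yolk syncytial layer list itself, and many hepatocyte and lipoprotein genes moved with it. The directions of these lists therefore depend on which libraries were left and do not bear on genotype. An estimated correlation was not used in these fits.

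The libraries of 24 hpf differed widely in these yolk genes within each genotype. The mean log2 CPM of the yolk syncytial layer markers ran from 2.74 to 5.66 in sib24 and from 2.12 to 5.99 in mut24, and was 4.25 ± 1.28 (SD, n = 4) against 3.93 ± 1.96, a difference of -0.32 (exact permutation p = 0.771, adjusted p = 0.771 over 10 tests). The lowest values were those of sib24 replicates 1 and 4 and mut24 replicates 2 and 4. At 48 hpf the range was 5.23 to 5.72 in sib48 and 4.68 to 4.92 in mut48.

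The largest changes at 24 hpf included many genes on the chromosomes that carry the targeted genes (assembly GRCz12tu). The rankings here cover called genes that passed the naming rule, with a symbol, at least 1 CPM and groups that did not overlap. Among the 6 largest increases were fosab, an immediate early gene (6.86-fold), CCKAR (2.57-fold), myof (2.77-fold from 12.6 ± 2.96 to 34.9 ± 5.43 CPM) and the monocarboxylate transporter gene slc16a8 (2.61-fold), and myof and slc16a8 lie on the chromosome of lipf. The 6 largest falls under this rule were those of taco1, lipf, pgap3 (6.85-fold), bbox1 of carnitine synthesis (4.01-fold), the mitochondrial ADP/ATP carrier gene slc25a4 (3.43-fold) and cpt1b. Of these taco1, lipf and pgap3 share a chromosome, as do gch2, pvalb2 and tefa. The taco1 transcript stood at 8.38 ± 2.12 CPM in sib24 and at 0.0313 ± 0.05 in mut24, where 5 reads were counted in the 4 libraries. Of 179 called genes with a chromosome, 39 (21.8%) lay on these 2 chromosomes, which held 6.73% of the tested genes (odds ratio 3.95, 95% interval 2.68 to 5.7, Fisher's exact p = 4.53e-11). The odds ratio was 3.44 for the chromosome of lipf (adjusted p = 9.3e-05) and 3.77 for that of pla2g15 (adjusted p = 8.9e-05), and 0 of 23 other chromosomes passed. Because under 80% of all tested genes had a chromosome, these odds ratios cover the genes with a match only. Fisher's exact test takes genes as independent, while genes measured in the same libraries can move together. Its p-values and interval may therefore overstate the certainty.

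In all, edgeR called 95 genes higher and 107 lower in mutants at 24 hpf, of which 20 and 24 changed at least 2-fold, and 8.52% of genes had groups that did not overlap, where chance gives 2.86%. The counts depended on single libraries: genes higher and lower were 22 and 40 without sib24 replicate 1, 32 and 52 without sib24 replicate 4, 42 and 52 without mut24 replicate 1, and 37 and 42 without mut24 replicate 2. They were 45 and 53 without mut24 replicate 3, and 316 and 146 without sib24 replicate 3. Of 27 named genes called at 24 hpf, 12 lost the call in at least 1 of these fits (bbox1, CCKAR, cyt1l, dnajc3a, fosab, insig1, per3, pfkma, serpinh1b, srebf2, tefa and tpi1b, with highest edgeR adjusted p-values from 0.0567 for tefa to 0.134 for dnajc3a), and none changed sign. Without the 4 libraries lowest in yolk syncytial layer markers, an alternative chosen after seeing the data, 6 genes were higher and 17 lower, and with these markers as a covariate 354 and 206, among them all 202 genes of the main test.

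At 48 hpf many lysosomal and sterol synthesis genes rose, as did the lipogenic regulator srebf1, while genes of fatty acid synthesis went both ways. Of 70 lysosomal genes, 22 were higher and 1 lower, which was lipf itself (32 and 1 when adjusted over the list alone). The lysosomal membrane gene lamp1a rose 1.91-fold from 48.3 ± 1.84 to 92.2 ± 4.91 CPM (edgeR adjusted p = 1.11e-07) and the peptidase gene tpp1 1.92-fold (edgeR adjusted p = 1.57e-06). Of 29 sterol synthesis genes 9 were higher and 0 lower (14 and 1 when adjusted over the list alone), with insig1 at 2.57-fold (edgeR adjusted p = 2.74e-05) and the lanosterol demethylase gene cyp51 at 2.66-fold. Among 32 genes of fatty acid and triglyceride synthesis 6 were higher and 2 lower (9 and 4 when adjusted over the list alone). Here srebf1 rose 3.82-fold from 88.4 ± 4.83 to 338 ± 62 CPM (edgeR adjusted p = 2.52e-08) and the desaturase gene fads2, which lies on the chromosome of pla2g15, rose 8.67-fold from 2.93 ± 0.634 to 25.4 ± 6.98 CPM (edgeR adjusted p = 1.11e-07). Camera called the lysosomal list (adjusted p = 5.39e-16) and the sterol list (adjusted p = 3.89e-07) up, with adjusted p = 0.195 and 0.321 with an estimated correlation. The synthesis list was not called (adjusted p = 0.12), and its median of -0.04 differed in sign from its mean of 0.16 and its direction, which was up.

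Among genes of energy metabolism, more were called lower than higher at 48 hpf, and most of those outside fatty acid oxidation were not called. Of 41 genes of fatty acid oxidation and Ppar targets, 18 were lower and 3 higher (21 and 3 when adjusted over the list alone). Among the lower genes were angptl4, an inhibitor of lipoprotein lipase, which fell 9.28-fold from 58.6 ± 2.92 to 6.31 ± 1.96 CPM (edgeR adjusted p = 2.93e-07), and pdk4, which fell 3.17-fold from 41.1 ± 3.96 to 13.0 ± 1.75 CPM (edgeR adjusted p = 4.95e-07). The 3 higher genes, chosen after their values were seen, were the receptor genes pparaa and pparab and fabp3. Of 35 genes of glycolysis and gluconeogenesis 10 were lower and 1 higher (11 and 2 when adjusted over the list alone), led by ldha (1.84-fold, edgeR adjusted p = 7.74e-05) and gpia (1.51-fold, edgeR adjusted p = 0.00411), both on the chromosome of pla2g15. Of 33 genes of oxidative phosphorylation 9 were lower and 0 higher (17 and 0 when adjusted over the list alone), including uqcrc1 (1.32-fold) and cycsb (1.43-fold). Of 12 mitochondrially encoded transcripts 4 were lower and 0 higher (9 and 0 when adjusted over the list alone), including mt-nd1 (1.34-fold) and mt-nd2 (1.3-fold). Camera adjusted p was 2.68e-12 for fatty acid oxidation, 0.0591 for glycolysis, 2.7e-08 for oxidative phosphorylation and 5.14e-05 for the mitochondrial transcripts. With an estimated correlation the adjusted p-values of the called lists were 0.178, 0.513 and 0.492. The share of counts from mitochondrial genes was 3.02 ± 0.194% in sib48 and 2.7 ± 0.0478% in mut48 (SD, n = 4, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.143 over 10 tests).

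**Figure D2:**
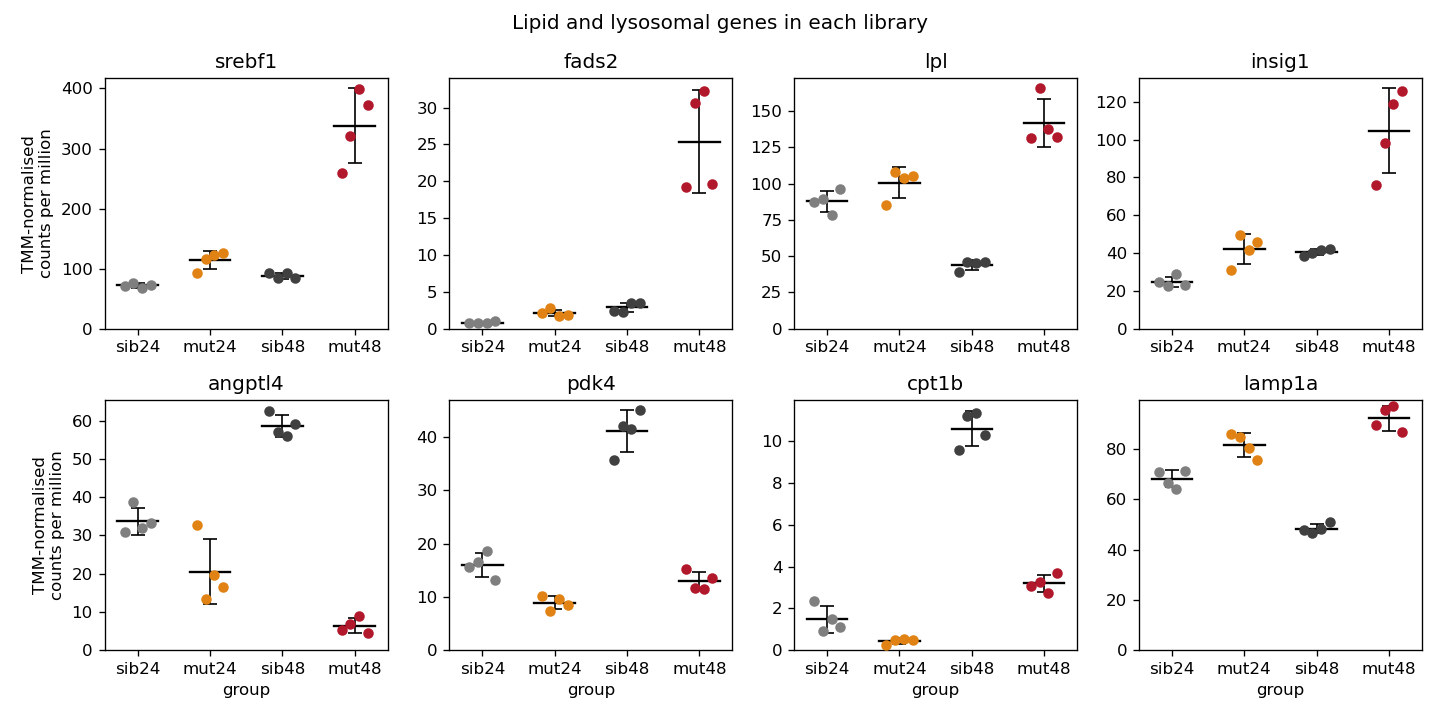
TMM-scaled CPM of 8 lipid and lysosomal genes on the vertical axis in each library, by group; points are libraries, bars the mean and whiskers 1 SD (n = 4). At 48 hpf all mutant values of srebf1, fads2, lpl, insig1 and lamp1a lie above those of siblings, and all mutant values of angptl4, pdk4 and cpt1b lie below.

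Genes that make and handle lipoproteins went both ways at 48 hpf. Of 28 lipoprotein genes 4 were higher and 1 lower (4 and 2 when adjusted over the list alone), and the list was not called (median log2 fold change -0.32, mean -0.49, direction up, adjusted p = 0.639). The lipoprotein lipase gene lpl rose 3.22-fold from 44.1 ± 3.36 to 142 ± 16.4 CPM (edgeR adjusted p = 1.41e-08) and the phospholipid transfer protein gene pltp 1.67-fold. Also higher, and named after their values were seen, were lcat, on the chromosome of pla2g15 (log2 fold change 1.00, edgeR adjusted p = 0.0229), and apodb (0.67, edgeR adjusted p = 0.0417). The apolipoprotein gene apoa4b.2 fell 85.3-fold from 24.1 ± 10.4 to 0.277 ± 0.165 CPM (edgeR adjusted p = 0.0214). Of 23 yolk syncytial layer markers 2 were lower and 0 higher (2 and 0 when adjusted over the list alone), apoa4b.2 and agr2 (2-fold, edgeR adjusted p = 0.00546), with adjusted p = 0.614 for the list. The mean log2 CPM of these markers was 5.47 ± 0.204 in sib48 and 4.86 ± 0.118 in mut48 (n = 4, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.143 over 10 tests). Of 25 Hnf4 and other hepatic transcription factors 4 were higher and 1 lower (4 and 1 when adjusted over the list alone), with rxraa 1.27-fold higher and prox1a 1.27-fold lower (camera up, adjusted p = 0.00379, and adjusted p = 0.29 with an estimated correlation). The other higher members, named after their values were seen, were cebpb, hnf1bb and nr0b2a. The factors hnf4a and hnf4b, named here for the title of the series, were not called, at 4.06 ± 1.9 against 5.85 ± 0.826 CPM (edgeR adjusted p = 0.411) and 3.44 ± 0.913 against 3.29 ± 0.992 CPM (edgeR adjusted p = 0.977). Of 30 hepatocyte and plasma protein genes only pah was called (1.23-fold higher; 0 when adjusted over the list alone; camera adjusted p = 0.334).

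A fit of the 48 hpf libraries alone, whose error estimate leaves out the wide spread at 24 hpf, called more lipoprotein genes. This alternative was planned for counts of genes and was extended to lists and named genes after seeing the data. It called 10 of 28 lipoprotein genes lower and 7 higher (camera adjusted p = 0.0551) and 9 of 23 yolk syncytial layer markers lower and 2 higher (camera down, adjusted p = 0.000947, against 0.614 in the main test and 0.928 there with an estimated correlation). Of 28 hepatocyte and plasma protein genes it called 7 higher and 2 lower (camera adjusted p = 0.0551). An estimated correlation was not used for the lists in this fit. The following genes were chosen after their values were seen, and their adjusted p-values are those of edgeR on the 8 libraries of 48 hpf. The apolipoprotein gene apoea was 12.1-fold lower, at 107 ± 31.7 CPM in sib48 and 8.57 ± 6.56 in mut48 (adjusted p = 0.000393, and 0.0575 in the main test), and apoa4b.1 was 2.73-fold lower, at 175 ± 28.5 and 62.4 ± 12.1 CPM (adjusted p = 0.000155, and 0.481 in the main test). The yolk syncytial layer gene afp4 was 4.98-fold lower (adjusted p = 2.55e-05, and 0.174 in the main test). Smaller falls were those of apoc2 (2.07-fold), apoeb (1.83-fold), pla2g12b (2.09-fold), fabp2 (2.3-fold) and mttp, which loads lipid onto apolipoprotein B (1.7-fold, adjusted p = 0.01). Higher were apobb.2 (2.26-fold, adjusted p = 0.00138) and the cholesteryl ester transfer protein gene cetp (2.64-fold, adjusted p = 0.00557). The abundant genes apobb.1 (1045 ± 289 against 720 ± 113 CPM, adjusted p = 0.105) and apoa1a (489 ± 94.9 against 435 ± 54.8 CPM, adjusted p = 0.618) were not called. Whether reads could pass between the close copies of the apoa4b, apoe and apobb genes depends on counting settings that are not given in the sources used here.

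**Figure D3:**
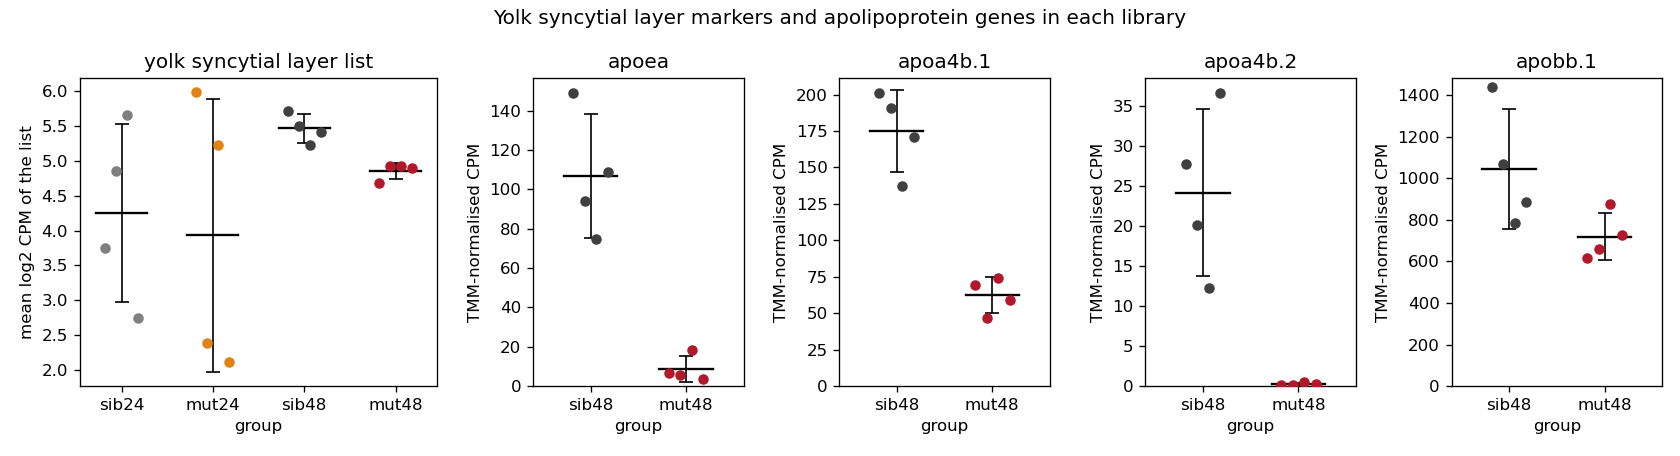
Mean log2 CPM of the yolk syncytial layer markers in all 4 groups, and TMM-scaled CPM of 4 apolipoprotein genes in sib48 and mut48; points are libraries, bars the mean and whiskers 1 SD (n = 4). The markers spread from 2.12 to 5.99 at 24 hpf and less at 48 hpf, where apoea, apoa4b.1 and apoa4b.2 are lower in every mutant library.

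Some genes of the Igf axis, of p53 response and of inflammation were higher at 48 hpf, while stress response genes went both ways. Of 29 genes of the insulin and Igf axis 7 were higher and 0 lower (10 and 1 when adjusted over the list alone), among them igfbp1b, which encodes an Igf-binding protein (7.81-fold from 0.346 ± 0.103 to 2.73 ± 1.82 CPM, edgeR adjusted p = 0.00231), and sesn1 (1.66-fold, edgeR adjusted p = 0.000386). Of 20 p53 targets, which also include sesn1, 5 were higher and 0 lower (7 and 0 when adjusted over the list alone), foxo3a by 1.31-fold. Of 38 genes of the endoplasmic reticulum and integrated stress response 10 were higher and 5 lower (14 and 11 when adjusted over the list alone). The stress transcription factors ddit3 (3.76-fold, edgeR adjusted p = 0.000371) and cebpg (1.52-fold) were higher, while the 5 lower members, chosen after their values were seen, were the chaperone and folding genes manf, dnajc3a, creld2, hsp90b1 and sdf2l1. This list had a median of -0.10, a mean of 0.13 and the direction up (adjusted p = 0.128). Of 22 genes of inflammation and the acute phase 6 were higher and 0 lower (11 and 0 when adjusted over the list alone), including c4b of complement (2.74-fold) and jun (1.43-fold). Of the mut48 libraries, replicate 3 was highest for c4b (43.5 CPM), jun (93 CPM) and ddit3 (112 CPM). Each kept its call in every fit without 1 library, with a lowest log2 fold change of 1.016, 0.392 and 1.505 in that order. Camera called the Igf list (adjusted p = 9.86e-06), p53 targets (adjusted p = 0.000185) and inflammation (adjusted p = 7.47e-07) up, with adjusted p = 0.195, 0.178 and 0.301 with an estimated correlation.

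Among genes that passed the naming rule, the largest increases at 48 hpf included ADP-ribosylation factor genes and some interferon-response genes. Neither kind of gene was tested as a list. The ADP-ribosylation factor gene arf4b rose 79.5-fold, from 0.231 ± 0.0477 to 18.5 ± 11.5 CPM (edgeR adjusted p = 6.48e-06), and a gene listed as ARF5 (1 of many) 12.6-fold (edgeR adjusted p = 0.00018). The interferon-response genes isg15 (36.3-fold), irf1b (23.6-fold) and tap1 (13.1-fold) were high mostly in mut48 replicate 3. Without that library the log2 fold change went from 5.18 to 3.33 for isg15 (edgeR adjusted p = 0.005), from 4.56 to 2.203 for irf1b (edgeR adjusted p = 0.0202) and from 3.72 to 1.42 for tap1 (edgeR adjusted p = 0.0855). Under the naming rule the 6 largest falls were those of apoa4b.2, taco1 (13.3-fold), rbp2a, a retinol-binding protein gene (10.4-fold), bbox1 (9.59-fold), tmem86b of lysophospholipid breakdown (9.56-fold, from 1.11 ± 0.573 to 0.115 ± 0.097 CPM) and lipf. The fall of taco1 depended on mut48 replicate 4, without which its log2 fold change went from -3.73 to -7.78.

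Some retinal and neuronal markers were lower and some endothelial markers higher at 48 hpf, each named one by less than 2-fold. Of 25 retina and photoreceptor genes 5 were lower and 0 higher (6 and 0 when adjusted over the list alone), with the photoreceptor factors otx5 (1.62-fold) and crx (1.7-fold). Of 25 neuronal genes 6 were lower and 0 higher (7 and 0 when adjusted over the list alone), with tubb5 (1.38-fold) and atp1a3a (1.32-fold). Of 42 skeletal muscle genes 2 were lower and 0 higher (2 and 0 when adjusted over the list alone), the actin gene acta1b (1.97-fold) and the myosin chaperone gene unc45b (1.71-fold). Over all genes edgeR called 1115 of 24300 lower at 48 hpf, so the share among muscle genes was near that of all genes. Of 23 endothelial genes 4 were higher and 0 lower (7 and 0 when adjusted over the list alone), with the scavenger receptor gene stab2 (1.89-fold) and the receptor kinase gene tie1 (1.51-fold). Camera adjusted p was 0.0134 for retina, 0.00234 for neuronal, 0.0788 for muscle and 1.2e-05 for endothelial genes, and with an estimated correlation the adjusted p-values of the called lists were 0.321, 0.513 and 0.178. Cell cycle genes were called in 2 of 46 cases, ccnb3 (1.33-fold higher) and mki67 (1.28-fold higher), and cartilage, bone and matrix genes in 2 of 33, sox9a higher and acana lower. By edgeR no lipid droplet gene (13 tested, plin6 with adjusted p = 0.0667) and no myeloid gene (22 tested, il34 with adjusted p = 0.113) was called. Of these 35, 7 had an unadjusted p under 0.05 and DESeq2 called 1. Camera called the myeloid list up (adjusted p = 0.0387, and adjusted p = 0.454 with an estimated correlation). Of 78 cytosolic ribosomal protein genes edgeR and DESeq2 called none, 3 had an unadjusted p under 0.05, and camera called the list up (adjusted p = 0.000103, and adjusted p = 0.899 with an estimated correlation).

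**Figure D4:**
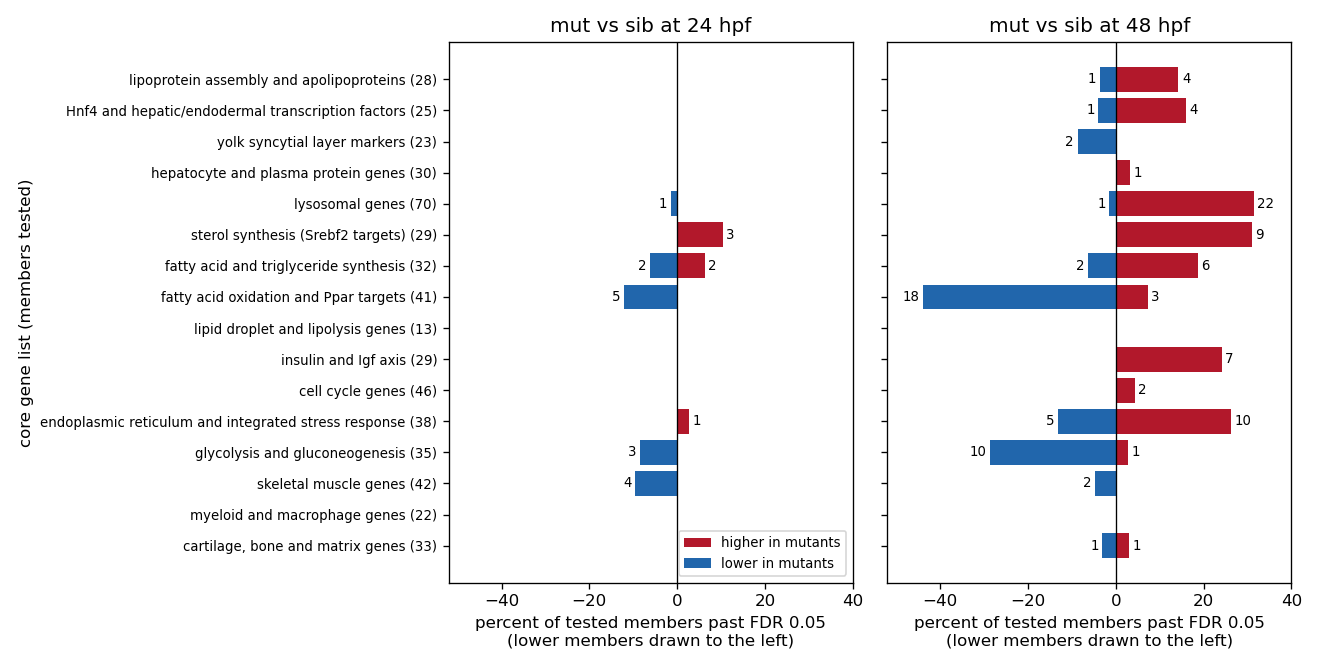
Percent of the tested members of each core list that edgeR called in mutants against siblings, at 24 hpf on the left and 48 hpf on the right; bars to the right of 0 are members higher in mutants, bars to the left members lower, and the printed counts are genes. At 48 hpf 22 of 70 lysosomal genes were higher and 18 of 41 genes of fatty acid oxidation lower.

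In all, edgeR called 691 genes higher and 1115 lower in mutants at 48 hpf, of which 141 and 156 changed at least 2-fold, and 14.2% of genes had groups that did not overlap, where chance gives 2.86%. The balance of the directions depended on processing: 38.3% of the calls were higher, 52.3% with upper-quartile scaling, and the fit of the 48 hpf libraries alone called 711 higher and 482 lower. Genes higher and lower were 353 and 483 without sib48 replicate 2, 428 and 707 without sib48 replicate 3, 395 and 537 without sib48 replicate 4, and 437 and 648 without mut48 replicate 2. Of 51 named genes called, 13 lost the call in at least 1 fit without a library (acana, apoa4b.2, ccnb3, crx, mki67, mt-nd2, pah, pltp, prox1a, rbp2a, sox9a, tap1 and tmem86b, with highest edgeR adjusted p-values from 0.0654 for apoa4b.2 to 0.137 for sox9a), and none changed sign. The chromosomes of lipf and pla2g15 held 8.11% of the 1603 called genes with a chromosome and 6.73% of the tested ones (odds ratio 1.25, 95% interval 1.03 to 1.51, Fisher's exact p = 0.025). As many top genes lay there in 3 of 35 splits of the libraries (130 in the real one, highest other 141), so chance is not excluded for this share at 48 hpf.

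The genes that differed at 24 hpf overlapped those of 48 hpf. Of the called genes, 21 were higher at both ages, where independent lists would share 2.7, and 34 lower at both, where they would share 4.91, while 5 went opposite ways against 7.4. Among those higher at both were srebf1, srebf2, insig1, fads2, cyp51, myof and slc16a8, and among those lower at both lipf, pdk4, cpt1b, bbox1, acacb, tpi1b, gpia, gch2 and pgap3. Of these, myof, slc16a8, lipf, gch2 and pgap3 lie on the chromosome of lipf, and fads2 and gpia on that of pla2g15. Calls of 24 hpf on these chromosomes kept their sign at 48 hpf in 92.1% of cases, against 64.3% elsewhere. The overlap was not counted without these chromosomes. Across all tested genes the correlation of the log2 fold changes was 0.0798 (Spearman 0.0985), as a description only, since genes are not independent replicates. The overlap depended on single libraries. Genes higher and lower at both ages were 9 and 15 without sib24 replicate 1, 12 and 17 without sib24 replicate 4, 10 and 13 without mut24 replicate 2 and 11 and 17 without mut24 replicate 3. Of single directions, 41 were higher at both without sib24 replicate 3, 22 lower at both without mut24 replicate 1 and 21 lower at both without sib48 replicate 2.

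The effect of genotype on several lipid genes differed between the ages by the interaction test. The lipase genes lipg and lpl gained 1.58 (SE 0.115, edgeR adjusted p = 1.21e-06) and 1.49 (SE 0.135, edgeR adjusted p = 1.81e-05) on the log2 scale from 24 to 48 hpf. In siblings lipg stood at 30.4 ± 2.38 and 25.4 ± 1.82 CPM at the ages, and in mutants at 37.2 ± 3.34 and 92.8 ± 5.25. The uncharacterised gene si:ch211-117k10.3 gained 2.498 (SE 0.159, edgeR adjusted p = 2.81e-07), and ppp1r3b, which directs a phosphatase to glycogen, lost ground with -1.68 (SE 0.15, edgeR adjusted p = 1.81e-05). In all 118 genes had a higher and 126 a lower mutant effect at 48 hpf. Of 70 lysosomal genes 5 were called up and 0 down (14 and 0 when adjusted over the list alone), and of 41 genes of fatty acid oxidation 5 down and 0 up (16 and 2 when adjusted over the list alone). Camera called these lists (adjusted p = 9.13e-07 and 1.54e-05), with adjusted p = 0.745 and 0.685 with an estimated correlation. The split depended on scaling, with 48.4% of these calls higher, 58.5% with RLE scaling (131 higher, 93 lower) and 65.8% with upper-quartile scaling (148 higher, 77 lower). Counts higher and lower were 69 and 53 without sib24 replicate 1, 70 and 60 without sib24 replicate 2 and 78 and 51 without sib24 replicate 4. They were 72 and 53 without mut24 replicate 1, 68 and 48 without mut24 replicate 2 and 65 and 53 without mut24 replicate 3. They were 52 and 31 without sib48 replicate 2 and 64 and 64 without sib48 replicate 3. The count lower alone moved to 209 without sib48 replicate 1, 64 without sib48 replicate 4, 190 without mut48 replicate 1 and 70 without mut48 replicate 2.

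Between 24 and 48 hpf siblings gained lens crystallin and neuronal transcripts and lost transcripts of cell cycle genes. Under the naming rule the largest increases were those of the lens crystallin genes crygm2d9, crygm2d16, crygm2d2 and crygm2d4, near-identical copies whose reads may be shared. At 24 hpf crygm2d9 and crygm2d16 had 0 reads, and at 48 hpf 136 ± 41.3 and 48.9 ± 5.67 CPM, at least 6910-fold and 2500-fold higher when 3 counts over the group are the floor. The Nodal antagonist gene lft2 (273-fold), the segmentation clock gene her1 (157-fold), the hatching enzyme gene he1.3 (140-fold) and lygl2 (78.5-fold) fell the most under the same rule. Of 46 cell cycle genes 45 were lower and 0 higher, led by mcm3 (3.68-fold), and of 78 ribosomal protein genes 76 were lower and 1 higher. Of 25 neuronal genes 24 were higher and 0 lower, of 39 lens crystallins 37 were higher and 0 lower, and of 35 genes of glycolysis and gluconeogenesis 23 were higher and 4 lower, led by gapdhs (6.81-fold). These counts were the same when adjusted over the list alone. Camera adjusted p was 4.19e-19, 4.26e-13, 2.29e-13, 6.33e-19 and 9.43e-05 in that order, and the adjusted p-values with an estimated correlation were 0.227, 0.824, 0.122, 0.122 and 0.227. Of 41 genes of fatty acid oxidation 21 were higher and 3 lower, and of 32 of fatty acid synthesis 17 and 4 (the same when adjusted over the list alone). Of 28 lipoprotein genes 6 were higher and 2 lower (3 and 2 when adjusted over the list alone). Other named genes went up: acadl of fatty acid oxidation (2.79-fold), agr2 (3.71-fold), apoda.1 (25.3-fold) and atp6ap1a of the lysosomal proton pump (3.43-fold). So did col1a1b (3.65-fold), foxo3b (3.33-fold), gpam (2.54-fold), ldlra (46.3-fold), npsn (11.8-fold), plin6 (7.04-fold), pvalb4 (21.2-fold) and slc7a5 (3.59-fold). Down went rxraa (1.92-fold) and uox (57-fold). Of 24300 genes edgeR called 8290 higher and 7093 lower in siblings, and 8279 higher and 7377 lower in mutants.

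No difference of mutants from siblings along this path of development passed the test, and a small delay is not excluded. With sib24 at 0 and sib48 at 1, mut24 lay at 0.0192 ± 0.0217 and sib24 at 0.0398 ± 0.0585 (SD, n = 4), a difference of -0.0206 (exact permutation p = 0.543, adjusted p = 0.762). At 48 hpf mut48 lay at 0.934 ± 0.0383 and sib48 at 0.971 ± 0.024, a difference of -0.0363 (exact permutation p = 0.171, adjusted p = 0.428). The mut48 replicates 1, 2 and 3 (0.9133, 0.8967 and 0.9426) lay below the lowest sib48 library (0.9432), and replicate 4 lay at 0.984. In no fit without 1 library did the difference of mutants and siblings at either age pass an unadjusted exact p of 0.05. Without mut48 replicate 4 the groups of 48 hpf did not overlap and still did not pass. With so few libraries the fits without 1 library therefore do not speak against a delay. A simulated delay of 0.1 was recovered as -0.0863 at 24 hpf and -0.0935 at 48 hpf. Simulated groups without an effect differed by at most 0.00557 and 0.00357. The simulated libraries varied gene by gene only and spread far less than the real ones. They therefore do not show how small a delay could be detected here.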

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

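The tests of yolk cell content, of developmental stage, of read sharing between paralogs, of a fall of all yolk markers by 1 factor, of the odds ratio on the chromosomes of lipf and pla2g15 and of the direction of these genes at 48 hpf, and of the distance of calls from lipf and pla2g15, were chosen only after the results were seen.

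Of 234 sets of 4 values checked, 15 held a library far from the others, where chance gives about 11.7, as chance flags about 1 in 20 groups. In mut48 replicate 3 this was so for il34 at 19.1 CPM (others 2.58 to 4.03), irf1b at 29.8 (1.1 to 2.13), isg15 at 22.5 (1.6 to 2.63) and tap1 at 13.1 (0.582 to 1.14). In sib48 replicate 4 it was so for crx at 99.5 CPM (others at most 74.4), crygm2d9 at 197 (109 to 120), otx5 at 118 (98.9 to 101) and plin6 at 20.4 (10 to 11.4). The other cases were agr2 at 27.5 CPM and pgap3 at 19.4 CPM in sib24 replicate 3 (others 16.9 to 17.3 and 10.6 to 12) and hsp90aa1.2 at 49.4 CPM in sib24 replicate 1 (43 to 43.6). So were pfkma at 1.18 CPM in mut24 replicate 2 (1.33 to 1.35), lpl at 39.1 CPM in sib48 replicate 1 (45.2 to 46.2) and taco1 at 2.1 CPM in mut48 replicate 4 (0.0212 to 0.0453). The last was the mean log2 CPM of yolk syncytial layer markers at 4.68 in mut48 replicate 1 (4.9 to 4.92).

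The effect of genotype differed between the ages, by the interaction test of edgeR, for 20 of the genes named for a genotype contrast or the interaction, and for acadl (-0.74), named for the contrast of ages. On the log2 scale the mutant effect was higher at 48 hpf by 1.58 for lipg, 1.49 for lpl, 1.27 for srebf1, 1.77 for fads2, 0.67 for lamp1a, 0.66 for tpp1, 0.51 for rxraa, 0.96 for tefa, 1.43 for slc25a4, 2.04 for ddit3, 6.22 for irf1b, 3.24 for ARF5 (1 of many) and 2.498 for si:ch211-117k10.3. The difference was -2.49 for angptl4, -0.82 for pdk4, -1.68 for ppp1r3b, -1.19 for agr2, -1.08 for dnajc3a, -1.66 for hsp90aa1.2 and -0.93 for krt5. The value of irf1b depends on mut48 replicate 3, without which its log2 fold change at 48 hpf went from 4.56 to 2.203.

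Calls at 24 hpf were concentrated on the chromosomes of lipf and pla2g15, with 39 of 179. Loss of the lipases acting wherever a gene lies is argued against as the whole cause by the odds ratio of 3.95, with a 95% interval of 2.68 to 5.7. Greater variation of these genes in general is argued against too, since 1 of 35 splits of the 8 libraries, the real one, had as many of its top genes there (highest other 27). Variants inherited together with the targeted alleles may account for these calls: 92.1% of those on the chromosomes (35 of 38) had the same sign at 48 hpf, against 64.3% of calls elsewhere (90 of 140, Fisher's exact p = 0.00056), and near lipf 17 of 300 genes within 150 genes were called against 2 of 390 beyond (Fisher's exact p = 5e-05). Near pla2g15 this was 12 of 300 against 7 of 299 (Fisher's exact p = 0.351), so the distance gave no answer there. These tests and the interval of the odds ratio take genes as independent, so they may overstate the certainty. No genotypes were at hand, and regulation by the targeted genes of their neighbours stays open and was not tested.

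Yolk syncytial layer genes and many lipoprotein genes spread widely among the 24 hpf libraries of both genotypes. The 23 yolk syncytial layer markers had a median range of 4.44 on the log2 scale (21.7-fold) against 0.734 for all genes. The range was not computed for the lipoprotein list, of which some members varied little, such as lpl (78 to 108 CPM). A difference in developmental stage is argued against as the whole cause, since the 8 positions between 24 and 48 hpf, found without these genes, spanned only 0.124. Within sib24 the positions over all genes did rise in the order of the marker mean (-0.0298, 0.0177, 0.0665 and 0.105), so stage is not excluded as a part. Libraries that hold different amounts of the yolk cell are a candidate explanation: 37 lipoprotein and plasma protein genes of at least 1 CPM outside the marker list had a median correlation of 0.972 with the marker mean over the 8 libraries, and 27 of them a correlation over 0.5. How embryos were handled is not stated, and a difference in the activity of these genes that moves them all together would give the same correlation, so it stays open.

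In the fit of the 48 hpf libraries alone, 10 of 28 lipoprotein genes and 9 of 23 yolk syncytial layer markers were lower in the mutants, while the test of all libraries called 1 and 2. The markers did not fall by 1 common factor, since 11 of 23 lay over 3 standard errors from their median of -0.50, from -6.38 to 1.33. This would argue against less yolk cell tissue as the whole cause only if the markers were made in the yolk cell alone. The list shares agr2 with the epidermal list, and rbp4, tfa, serpina1 and serpina1l with the hepatocyte list. The test therefore does not decide, and less yolk cell tissue stays open. Reads moved to the paralog are argued against as the whole cause for 2 pairs. The summed CPM of apoa4b.2 and apoa4b.1 in mutants was 0.315 times that of siblings and that of apoea and apoeb 0.41 times. Both sums were lower in all 4 mutant libraries (exact permutation p = 0.0286, the smallest possible). The copies apoa4b.1 (175 CPM in sib48, 62.4 in mut48) and apoeb (290 and 154 CPM) were lower too. The sums therefore cannot tell whether a part of the reads moved, which stays open. For apobb.1 and apobb.2 the ratio of 0.723 (exact permutation p = 0.114) left moved reads open. Loss of the lipases stays open as the biological explanation, as does a variant near these genes that differs between the genotypes, which was not tested.

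By the count of splits, a chance assignment of these libraries to groups is argued against for the genes called at 48 hpf. There 1 of 35 splits, the real one, gave as many (1806, highest other 1), which is the smallest share possible. A difference of clutch or pool between the groups would give the same and is not excluded. For the ages, too, only the real split gave as many, in siblings (1 of 35, 15383, highest other 0) and in mutants (1 of 35, 15656, highest other 1). For the overlap of the ages only the real split gave as many (1 of 100 drawn from 2450, 55, highest other 0). At 48 hpf the highest count of any other split was 1 gene, so regrouped libraries had almost no calls to share. The splits therefore cannot show that the overlap exceeds chance. For the interaction 2 of 100 splits drawn from 2450, the real one among them, gave as many (244, highest other 401). This share was under 0.05, but it rests on a draw, and another split called more genes than the real one. The interaction also holds the 24 hpf libraries, so chance is not firmly excluded for it. At 24 hpf chance cannot be excluded this way, since 2 of 35 splits gave as many (202, highest other 421), and the other split parted the 4 libraries lowest in yolk syncytial layer markers from the rest, which points to a structure of the samples. Nor can it be for the number of lists called by camera, with 5 of 35 splits at 24 hpf (15, highest other 18) and 11 of 35 at 48 hpf (14, highest other 22).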

How the results depend on the processing

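The yolk syncytial layer covariate, the fits without 4 libraries, the removal of genes linked to lipf and pla2g15 and the fit of 2 groups for named genes and lists were chosen only after results were seen. Small changes were mostly missed: on simulated data 30.9% (24 hpf) and 23.5% (48 hpf) of changes of 0.5 on the log2 scale were recovered. Counts that moved by over 1.5 times follow as genes higher and lower, or 1 of these, and unless stated the cause was not tested. With upper-quartile scaling 77 were lower in the interaction, without a filter 573 lower at 48 hpf and 51 lower in the interaction, and with the replicate block 55 and 42 in the interaction. The stricter rule of an absolute log2 fold change of at least 1 by its construction gave 20 and 24 at 24 hpf, 141 and 156 at 48 hpf, 5373 and 2463 for age in siblings, 5445 and 2757 in mutants and 42 and 40 in the interaction, and an odds ratio on the lipf chromosome at 48 hpf of 2.42 (adjusted p = 0.0475), where 1 of 23 other chromosomes passed too, with an odds ratio of 2.7 (adjusted p = 0.00618). The fit of only the 2 groups compared gave 64 lower at 24 hpf and 482 lower at 48 hpf. DESeq2 gave 383 and 457 at 24 hpf, 1044 higher at 48 hpf, 470 and 446 in the interaction and 70 and 71 in the overlap, and shared 198 of 202 and 1788 of 1806 edgeR calls with 0 opposite. The yolk syncytial layer covariate gave 354 and 206 at 24 hpf, 201 and 282 in the interaction and 51 higher at both ages. Without the 4 libraries lowest in these markers 6 and 17 were left at 24 hpf, and without the 4 highest 268 were higher.

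Leaving out 1 library at a time gave 22 to 316 higher and 40 to 146 lower at 24 hpf and 353 to 740 and 483 to 1241 at 48 hpf. It gave 52 to 149 and 31 to 209 in the interaction, 9 to 41 and 13 to 37 in the overlap. For age it gave 7734 to 8113 and 6693 to 7075 in siblings, and 7798 to 8128 and 7058 to 7195 in mutants. The lists of yolk syncytial layer markers, hepatocyte genes and oxidative phosphorylation at 24 hpf turned up by camera without the 4 lowest libraries (adjusted p = 0.000339, 0.000219 and 0.0069), and were down without the 4 highest (adjusted p = 2.18e-05, 4.8e-06 and 8.85e-10), as was the lipoprotein list (adjusted p = 0.000162). The marker list itself chose these libraries. Its direction, and that of lists that move with it, depends on which libraries were left and does not bear on genotype. With fry 14 of 15 list calls were lost at 24 hpf, 2 of 14 at 48 hpf and 14 of 14 in the interaction, and with an estimated correlation all were lost. Camera lost calls of 2 of 15 lists at 24 hpf without the linked genes, 2 with the replicate block, 2 with the covariate, 2 without the 4 lowest libraries and 7 without the 4 highest. It lost 1 of 14 at 48 hpf in the fit of 2 groups, and 1 of 14 in the interaction with the block and 1 with the covariate. Of 27 named genes called at 24 hpf, 27 kept the call with RLE scaling, 26 without a filter, 25 with the block, 21 in the fit of 2 groups and 27 with DESeq2. Of 51 at 48 hpf, 50, 50, 48, 45 and 49 did. Without the 4 libraries lowest in yolk markers only 4 of the 27 named genes of 24 hpf kept the call and 23 lost it, and without the 4 highest 19 kept it and 8 lost it. Both fits held fewer libraries of 24 hpf, so a lost call need not mean that the difference was absent.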

Other observations

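The members named here were chosen only after their values were seen, and the list counts were planned.

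Genes of phospholipid and lysophospholipid remodelling moved both ways at 48 hpf, with 3 of 29 higher and 3 lower (3 and 3 when adjusted over the list alone). The lysophospholipid transporter genes mfsd2aa and mfsd2ab were higher by 1.48 and 0.80 on the log2 scale (edgeR adjusted p = 4.29e-05 and 0.000997), with the choline kinase gene chka, while mboat7, chkb and lypla2 were lower. At 24 hpf edgeR called none of the 29, 9 had an unadjusted p under 0.05 and DESeq2 called 2. Of 18 pigment cell genes 3 were higher at 48 hpf (slc45a2, tfec and tyrp1a) and 2 lower (gch2 and pmelb), 4 and 4 when adjusted over the list alone. Clock genes were called up in 2 of 31 cases (2 when adjusted over the list alone), bhlhe40 and dbpb. Of 20 neural progenitor genes notch1a and vim were higher (4 higher and 1 lower when adjusted over the list alone), and of 14 notochord genes col8a1a and ntd5 lower (3 when adjusted over the list alone). Of 29 epidermal genes krt8 was higher and agr1 and agr2 lower (1 and 2 when adjusted over the list alone).

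Heart genes (14 tested), enterocyte genes (12) and pancreas genes (14) were not called by edgeR at either age. At 24 hpf 0, 1 and 0 of them had an unadjusted p under 0.05 and DESeq2 called 0 of each. At 48 hpf 1, 1 and 3 of them had an unadjusted p under 0.05, and DESeq2 called 0, 0 and 1. When adjusted over the list alone, 1 enterocyte gene was lower at 24 hpf. Of 13 maternal transcripts none was called in mutants at 48 hpf by edgeR or DESeq2, and 1 had an unadjusted p under 0.05. No vitellogenin gene passed the filter on low counts.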
